A study of Hydra viridissima with 4 samples.

How the data were processed

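Chromatin accessibility was profiled by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in whole animals of the green hydra Hydra viridissima, clone 2. Per the labels' protocols, each library came from a cell suspension of 50 large, budless animals, and nuclei were tagged with a commercial ATAC kit whose lysis volumes were doubled. The 4 libraries fall into 2 groups of 2 biological replicates, aposymbiotic and green (symbiotic). Groups were taken from the condition given in the labels and replicate numbers from the same labels.

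Per the submitters' processing notes, Trim Galore 0.6.10, Bowtie2 2.5.4, deepTools and MACS3 3.0.4 were used. Their settings, the genome assembly and any annotation are not given in the sources used here. The authors deposited 1 narrowPeak list per library, so peaks were called in each library separately. In these deposited lists each peak carries a fold enrichment, a ratio of the summit pileup to a background estimated by the caller without a control library. The deposited lists also carry the -log10 p-value and the -log10 q-value of each summit, and a score that is 10 times the -log10 q-value as a whole number. The lowest deposited -log10 q was just above 2 in every list, which corresponds to a q threshold of 0.01. The deposited position of each summit is an offset in bp from the peak start. A peak with several summits is repeated on 1 line per summit, and lines with the same start and end were counted here as 1 peak with the values of its strongest summit. Peak names carry a date-like tag. Read as month and day, it is 8 and 17 for aposymbiotic replicate 1, 8 and 18 for symbiotic replicate 1, 8 and 31 for aposymbiotic replicate 2, and 9 and 1 for symbiotic replicate 2.

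The total number of reads per library is unknown. The background tag pileup was recovered from the fold enrichments, which take equal steps in each list because the caller divides a whole pileup plus 1 by the background plus 1. The recovered pileup and background returned the listed -log10 p within 0.001 for 39.0%, 34.2%, 31.7% and 30.8% of the peaks of aposymbiotic replicate 1, symbiotic replicate 1, aposymbiotic replicate 2 and symbiotic replicate 2, which are peaks whose local background equalled that of the whole genome. For regions named in the text, the pileup and the local background were solved from the fold and the p-value of the peak. A tag is a fragment or an extended read, since the labels do not say which was piled up. Recovered pileups carry counting error, and a region without a peak has no value.

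Peaks of the 4 lists were merged into union regions wherever they shared at least 1 bp, and a region was called in a library when a peak of that library overlapped it. Folds and scores of separately called lists were used to describe and rank peaks within a list and were not tested between lists. Regions of 1 condition were those called in both libraries of that condition and in neither of the other. The overlap of lists was measured with the Jaccard index in bp. Agreement of the 2 replicate pairs was measured over regions called in exactly 1 library of each pair, as an odds ratio with a 95% Woolf interval and a two-sided Fisher's exact test. Regions are not independent replicates, so these p-values, and those of permutation tests over regions, describe these 4 libraries. Numbers of peaks were compared by a two-sided exact permutation test, whose smallest possible p with 2 libraries per group is 0.333. The named regions follow a rule fixed before the data were examined. Per condition they are the 10 regions with the highest lower percentile of fold enrichment in the 2 lists, and for regions called in all 4 lists the 5 with the highest lowest percentile. The alternatives were a -log10 q of at least 5, lists of equal length (the 21481 strongest peaks of each list), windows of 200 bp around summits, other overlap rules, a stricter presence rule, stratified odds ratios, crossed replicate pairs, and leaving out each library.

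Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated lists of 40000 regions with background pileups set for each library. Without a condition effect the agreement odds ratio was 1.03 (95% interval 0.856 to 1.23). With 1000 regions per condition raised 3-fold it was 3.45, and 316 symbiotic and 391 aposymbiotic planted regions were called as regions of their condition. Apart from the raised regions, the simulated libraries had the same true folds, and peaks were called by p-value and not by q-value. The simulation therefore does not cover folds that differ between conditions over all regions, as they did at shared regions here. Motifs, GC content, gene annotation and gene lists had been planned on the condition that a genome and annotation were given. They were not analysed here, so regions are reported by scaffold and position only, with coordinates counted from 1.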

Results

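Green hydra carries unicellular algae inside the epithelial cells of its gut lining, and aposymbiotic animals are those without the algae. Open chromatin was mapped in 2 aposymbiotic and 2 symbiotic libraries made from whole animals of 1 clone. The comparison asks which genomic regions are accessible with and without the symbiont. The lists held 21481 peaks in aposymbiotic replicate 1, 31072 in symbiotic replicate 1, 78594 in aposymbiotic replicate 2 and 87128 in symbiotic replicate 2. The background pileup, which rises with sequencing depth, was 9.39 and 6.80 tags in the aposymbiotic and symbiotic libraries of replicate 1, and 16.7 and 13.5 tags in those of replicate 2. If the tags in the peak names are read as dates, both libraries of a replicate number were handled 1 day apart and the symbiotic library came later in both numbers, so day and condition cannot be told apart. The genome assembly is not given in the sources used here, and positions refer to the scaffolds of the deposited lists.

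Symbiotic lists were longer than aposymbiotic lists within both replicate numbers, although their background was lower. The number of peaks was 1.45 times higher with the symbiont in replicate 1 and 1.11 times higher in replicate 2. Peaks covered 4.19 Mb against 5.23 Mb in replicate 1 and 14.98 Mb against 18.5 Mb in replicate 2, again with the higher value in symbiotic animals. Replicate 2 lists were longer than replicate 1 lists by a far wider margin, 3.66-fold in aposymbiotic and 2.80-fold in symbiotic animals. The group means were therefore 50037.5 ± 40385 peaks (SD, n = 2) in aposymbiotic and 59100 ± 39638 peaks (SD, n = 2) in symbiotic animals, a difference within the spread of replicates (log2 ratio 0.24, two-sided exact permutation p = 0.667). With 2 libraries per group this test cannot give a p below 0.333.

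**Figure D1:**
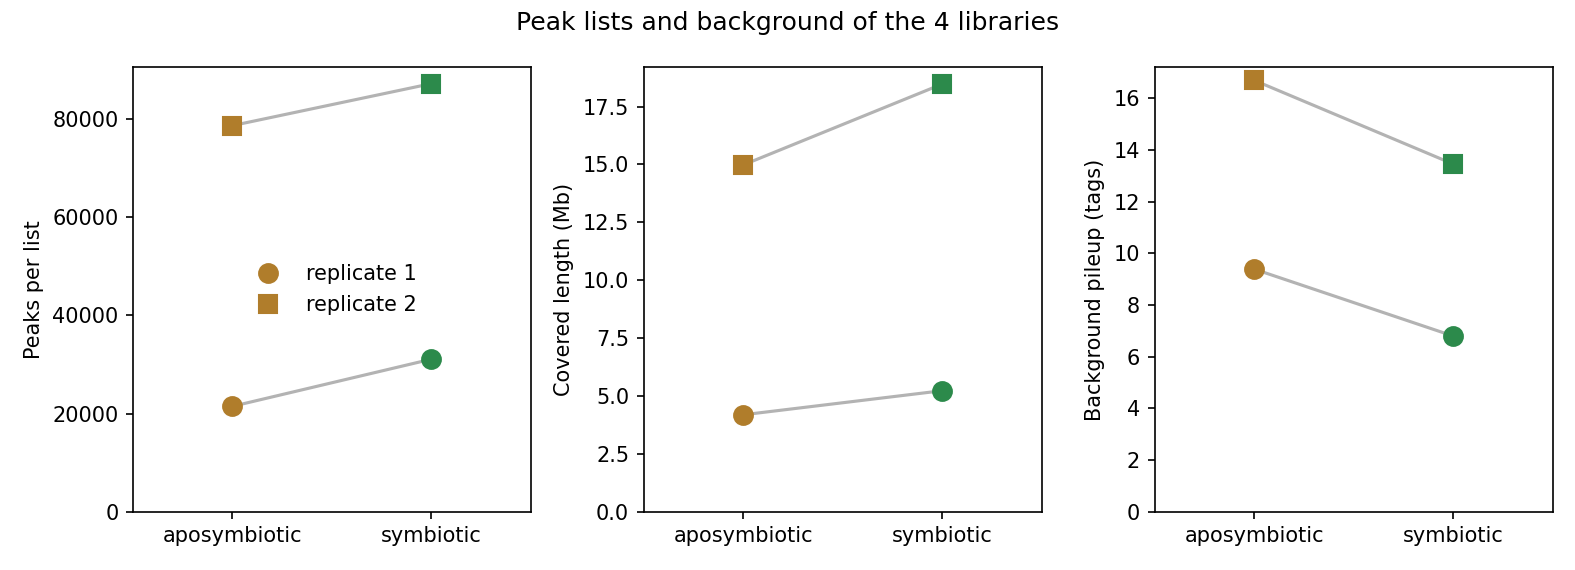
Number of peaks, covered length in Mb and background pileup in tags (y axes, from 0) for each library, by condition (x axes); circles are replicate 1, squares are replicate 2, and grey lines join libraries with the same number. In both numbers the symbiotic list is longer (31072 against 21481 and 87128 against 78594 peaks) while its background pileup is lower (6.80 against 9.39 and 13.5 against 16.7 tags).

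Merging the lists gave 117973 regions, of which 10256 were called in all 4 libraries and 61443 in a single library. Regions shared by all 4 libraries were strong, with median folds of 2.98 and 3.01 in aposymbiotic replicates 1 and 2 and of 3.49 and 3.48 in symbiotic replicates 1 and 2. Regions called in both symbiotic lists only had a median width of 197 bp, and those called in both aposymbiotic lists only 196.5 bp. The strongest shared region lay on scaffold 1 at 30802248 to 30802387, with a fold enrichment of 23.9 and 21.8 in aposymbiotic replicates 1 and 2 and of 29.7 and 20.3 in symbiotic replicates 1 and 2. These folds correspond to 247, 385, 231 and 292 tags at the summit. The other named shared regions were on scaffold 11 at 10047651 to 10048597, scaffold 4 at 1436806 to 1437493, scaffold 12 at 9321122 to 9321707 and scaffold 1 at 11101299 to 11101734. Across all 5, folds ranged from 11.98 to 29.7 over the 4 libraries.

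With lists as deposited, the Jaccard index was higher within replicate number than within condition. Lists of unlike length cannot reach a high index. Covered length differed 3.57-fold and 3.53-fold between lists of the same condition, and 1.25-fold and 1.23-fold between lists of the same number. This order as deposited therefore does not by itself show likeness by replicate number. The Jaccard index was 0.236 between the replicate 1 libraries and 0.347 between the replicate 2 libraries. It was 0.173 between the aposymbiotic libraries and 0.198 between the symbiotic libraries, and 0.149 and 0.194 between libraries that shared neither condition nor number. When each list was shortened to its 21481 strongest peaks, the index was 0.248 between the replicate 1 libraries, below the 0.261 of the aposymbiotic and the 0.252 of the symbiotic libraries, and 0.284 between the replicate 2 libraries. It was 0.223 and 0.241 between libraries that shared neither. The mean share of the shorter list that overlapped the other list was 79.0% for the same condition, 75.02% for libraries sharing neither and 58.6% for the same number. A long list overlaps more of a short list, so these shares are raised in pairs of unlike length. Aposymbiotic replicate 1 with symbiotic replicate 2, sharing neither, had 79.8%, against 77.2% for the aposymbiotic pair. At equal length the mean shares were 49.2% for the same condition, 45.3% for neither and 46.4% for the same number. This order was not tested, since the 3 ways to pair 4 libraries allow no exact permutation p below 0.333.

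A total of 3700 regions were called in both symbiotic and neither aposymbiotic library, and 1204 regions in both aposymbiotic and neither symbiotic library. The median within-list percentile of fold was 35.9 and 49.0 for the symbiotic regions in symbiotic replicates 1 and 2. It was 39.3 and 56.7 for the aposymbiotic regions in aposymbiotic replicates 1 and 2. For regions called in all 4 libraries it was at least 69.1. The symbiotic regions had median folds of 2.70 and 2.49, and the lowest folds called over the genome-wide background were 2.43 and 1.94. The named regions below are the strongest and not typical of these sets. Together these 4904 regions compare with 2567 regions called in exactly 1 aposymbiotic and 1 symbiotic library with different numbers, and with 24058 regions that separated the replicate numbers, of which 23755 were called in the replicate 2 libraries only. The surplus of symbiotic regions was 3.07-fold, and at a -log10 q of at least 5 there were 1747 symbiotic and 462 aposymbiotic regions. Without aposymbiotic replicate 1 the direction reversed, to 4313 symbiotic and 25440 aposymbiotic regions, and without symbiotic replicate 2 there were 7350 and 5761. Trimming lists to equal length brings the counts of the conditions towards balance by construction. With all lists at equal length the counts were 1957 symbiotic and 1768 aposymbiotic regions, and with lists of equal length within each replicate number they were 1992 and 1535. At equal length, 3725 regions separated the conditions, 3166 separated the replicate numbers and 2443 separated the crossed pairs.

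**Figure D2:**
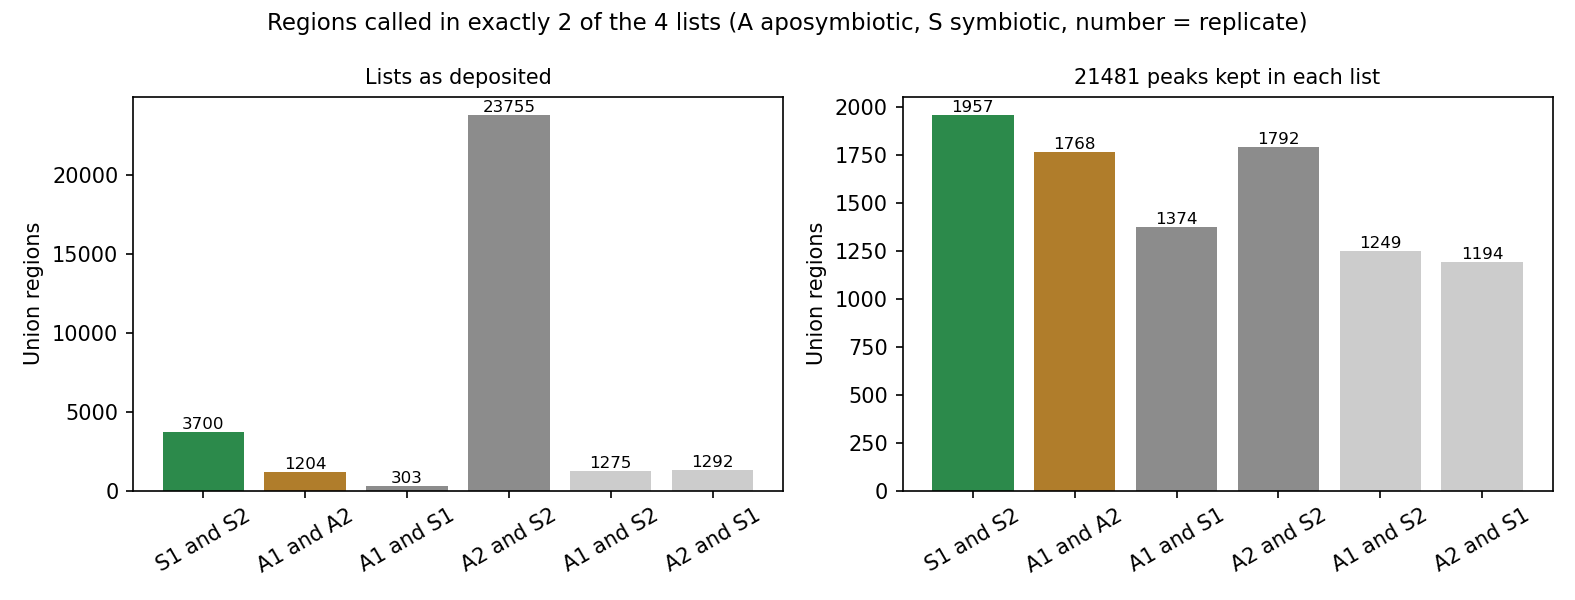
Number of union regions (y axes, from 0, with different scales) called in exactly 2 of the 4 lists, by which 2 (x axes; A aposymbiotic, S symbiotic, number the replicate); green and brown bars are the regions of 1 condition. With lists as deposited the 23755 regions of the 2 replicate 2 lists exceed all other bars, and with 21481 peaks per list the symbiotic (1957) and aposymbiotic (1768) bars stand above the crossed bars (1249 and 1194).

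Among regions called in exactly 1 library of each pair, those symbiotic in replicate 1 were mostly symbiotic in replicate 2. Those aposymbiotic in replicate 1 were divided about evenly between the conditions in replicate 2. Many regions fall outside this comparison. Of those called in symbiotic but not aposymbiotic replicate 1, 9205 were called in both replicate 2 libraries and 3650 in neither. For aposymbiotic but not symbiotic replicate 1 these counts were 4557 and 2080. Among the 4992 regions that were symbiotic in pair 1 and called in 1 library of pair 2, 74.1% were symbiotic in pair 2. Among the 2479 that were aposymbiotic in pair 1, 51.4% were symbiotic in pair 2. The odds ratio was 2.70 (95% interval 2.44 to 2.99, two-sided Fisher's exact p = 1.66e-83 over 7471 regions). Of the 37065 regions that only symbiotic replicate 2 held in its pair, 11.6% were called in symbiotic and 5.09% in aposymbiotic replicate 1. Of the 27102 regions that only aposymbiotic replicate 2 held, 6.13% were called in symbiotic and 5.81% in aposymbiotic replicate 1. With the pairs crossed, aposymbiotic replicate 1 with symbiotic replicate 2 and the reverse, the odds ratio was 0.619 with lists as deposited and 1.41 at equal length. Regions held by both replicate 2 libraries were called in 40.7% of cases in symbiotic and 31.01% in aposymbiotic replicate 1.

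The strongest region found only in symbiotic animals was on scaffold 1 at 41423632 to 41423786. Its fold enrichment was 8.20 in symbiotic replicate 1 (63 tags at the summit) and 5.26 in symbiotic replicate 2 (75 tags). Another region of scaffold 1, at 41434312 to 41434401, had folds of 6.66 and 4.15 and ended 632 bp before the end of the last peak of that scaffold. The region on scaffold 6 at 3607400 to 3607645 reached the highest fold of the set, 12.4 in replicate 1 (96 tags), and 5.19 in replicate 2 (74 tags). Regions called in exactly 1 aposymbiotic and 1 symbiotic library with different numbers reached 14.1 and 4.77 in symbiotic replicates 1 and 2. In aposymbiotic replicates 1 and 2 they reached 4.14 and 9.72. A high fold in a region called in only 2 lists is thus not by itself a mark of condition. On scaffold 3 at 11001105 to 11001227 the folds were 6.15 and 5.40, and on scaffold 10 at 2642507 to 2642625 they were 5.64 and 5.46. The remaining named symbiotic regions were on scaffold 9 at 14246639 to 14246814, scaffold 1 at 20818296 to 20818389, scaffold 8 at 8517883 to 8517997, scaffold 12 at 11132797 to 11132929 and scaffold 2 at 1637399 to 1637506. The lowest of the 20 folds was 3.62. The lowest folds called over the genome-wide background were 2.21 in aposymbiotic replicate 1 and 1.87 in aposymbiotic replicate 2.

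The strongest region found only in aposymbiotic animals was on scaffold 2 at 21898879 to 21899001, with folds of 5.77 (59 tags) and 5.20 (91 tags) in replicates 1 and 2. The next was on scaffold 8 at 15706373 to 15706495, with folds of 5.39 and 4.69. On scaffold 12 at 13183528 to 13183677 the folds were 5.29 and 5.03, and on scaffold 10 at 8509143 to 8509283 they were 5.20 and 5.48. Scaffold 2 held 2 more named aposymbiotic regions, at 12182754 to 12182937 and at 15370635 to 15370802. Scaffold 4 held 3, at 7594538 to 7594683, 13016797 to 13017137 and 10231014 to 10231122, and scaffold 8 held another at 14171183 to 14171359. Their lowest fold was 3.11, and the lowest folds called over the genome-wide background were 2.43 and 1.94 in symbiotic replicates 1 and 2. All 10 named regions of each condition stayed regions of that condition with summit windows. No region was tested on its own, since the lists hold no value where no peak was called.

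**Figure D3:**
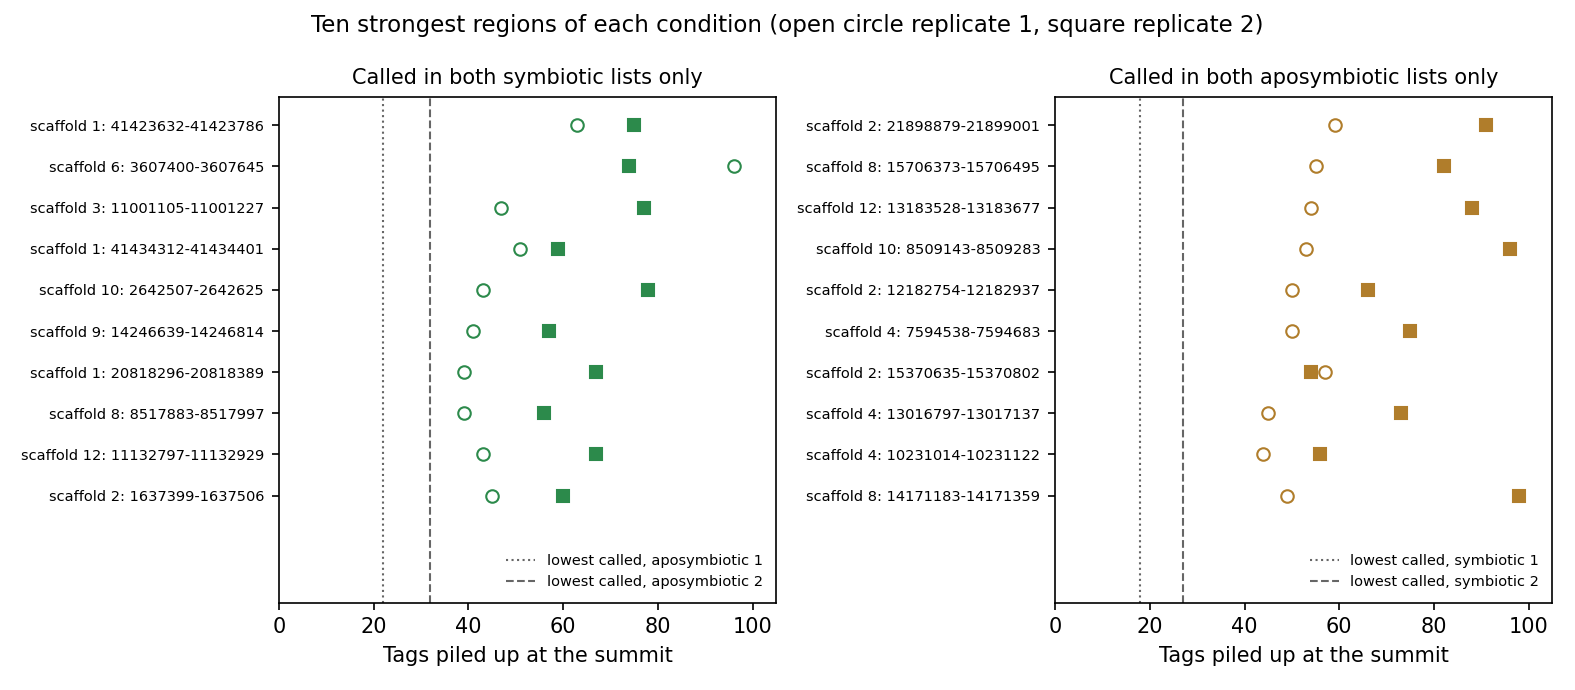
Tags piled up at the summit (x axes) of the 10 strongest regions called only in symbiotic (left) and only in aposymbiotic (right) libraries, one region per line; open circles are replicate 1 and filled squares replicate 2, and vertical lines mark the lowest pileup called over the genome-wide background in the libraries of the other condition, not scaled for depth. All points lie to the right of both lines of their panel, which stand at 22 and 32 tags on the left and at 18 and 27 tags on the right.

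Regions of both conditions were spread over the large scaffolds. The 14 scaffolds with at least 1000 union regions each held 99.4% of all regions, at 229 to 529 regions per Mb of scaffold up to the last peak. Symbiotic regions made up between 69.5% (scaffold 14) and 78.4% (scaffold 8) of the regions of 1 condition on these scaffolds, and this share did not differ detectably between scaffolds (permutation test over regions with 100000 resamples, p = 0.297). Scaffold 8 held 337 symbiotic and 93 aposymbiotic regions, and scaffold 14 held 57 and 25. Scaffold 1, on which peaks reached 41.4 Mb, held 402 and 120. The highest count of symbiotic regions in a window of 100 kb was 8, on scaffold 8 at 200001 to 300000 and at 2400001 to 2500000. It was not above chance, since the highest window reached 8 regions at the median of 10000 permutations (p = 0.718). For aposymbiotic regions the highest window, scaffold 5 at 18400001 to 18500000, held 5, which was also the permuted median (permutation p = 0.529). No scaffold had peaks in both symbiotic libraries and in neither aposymbiotic library.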

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

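Several tests were chosen after seeing the data. These used lists of equal length within replicate number, width strata and, at equal length, crossed pairs and the share of the shorter list. Distances and named regions under other settings were also chosen then. The tests of distance to shared regions, of region width, of windows of 100 kb and of the symbiotic share between scaffolds had not been planned. Crossed pairs with lists as deposited had been planned. The agreement of replicate pairs stayed above 1 and past the threshold under 8 alternatives, with odds ratios from 1.41 to 4.15. Without the replicate block, that is with pairs crossed and lists as deposited, it reversed to 0.619, where 23755 regions were held by both replicate 2 lists and neither replicate 1 list. With the replicate block the log2 ratio was 0.34 for peak number and 0.31 for covered length, with an exact sign-flip p = 0.5, the smallest that 2 pairs allow. Deviations of same-numbered libraries correlated over regions at -0.102 as deposited and 0.0333 at equal length. A union region needs at least 1 call, which pulls this correlation down. It therefore cannot show whether same-numbered libraries vary together.

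The difference in Jaccard index, same condition minus same number, was -0.106 as deposited, -0.140 at a -log10 q of at least 5 and -0.00937 at equal length. As a share of the shorter list it reversed to 0.204, to 0.0830 with 50% reciprocal overlap and to 0.0277 at equal length. As deposited, same-condition pairs set a short list against a long list, which by itself lowers the Jaccard index and raises this share. The cause of the reversal at equal length was not tested. Symbiotic regions fell from 3700 to 1747 at the stricter q, 1957 at equal length, 1992 at equal length within number and 523 when calls had to pass the stricter q and the other condition had no peak in its full lists. Aposymbiotic regions fell from 1204 to 462 at the stricter q and 200 under that last rule. Their log2 ratio was 1.62 as deposited, 0.15 at equal length and 0.38 at equal length within number. Trimming brings the counts towards balance by construction. The median distance to shared regions, symbiotic minus aposymbiotic, reversed to -846.5 bp at the stricter q; the cause was not tested.

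Leaving out 1 library breaks the balance of long replicate 2 and short replicate 1 lists. The log2 ratio of peak number was -0.41 without aposymbiotic replicate 1, -0.69 without symbiotic replicate 2 and up to 1.46 without aposymbiotic replicate 2. For covered length it was -0.34, -0.87 and 1.499 without the same libraries. Symbiotic and aposymbiotic regions numbered 4313 and 25440 without aposymbiotic replicate 1, 35177 and 1574 without symbiotic replicate 1, 12905 and 3284 without aposymbiotic replicate 2, and 7350 and 5761 without symbiotic replicate 2. Their log2 ratio ranged from -2.56 without aposymbiotic replicate 1 to 4.48 without symbiotic replicate 1. Motif, GC, annotation and gene list analyses were not run, because no genome or annotation was used here. Reciprocal overlap was not run for union regions, where summit windows took its place.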

Other observations

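The tests of background pileup, of sequences without aposymbiotic peaks, of preparation day, of list length within replicate number, of the lowest fold called, of width strata, of independent sampling, of neighbouring regions and of the distance under other settings, the count of named regions clear of the limits and the 0.5 added to each count were chosen after the results were seen. The small scaffolds described here were also chosen after their values were seen. Scaffolds 15 to 20, on which peaks reached between 1.04 and 10.6 Mb, held 676 union regions, or 13.5 to 74.7 per Mb, against at least 229 per Mb on the 14 large scaffolds. On these 6 scaffolds the symbiotic list had 1.70 times as many peaks in replicate 1 (230 against 135) and 2.02 times as many in replicate 2 (496 against 245), against 1.45 and 1.11 on the large scaffolds. Scaffold 86, with peaks up to 15225 bp, was covered by peaks over 14.6% and 26.2% of that length in aposymbiotic replicates 1 and 2 and over 13.7% and 32.3% in symbiotic replicates 1 and 2, against at most 8.35% on the 14 large scaffolds, reached on scaffold 2 in symbiotic replicate 2. Scaffold 151 had 2 peaks, both in aposymbiotic replicate 1.

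Regions called only in both aposymbiotic lists lay closer to regions shared by all 4 libraries than those called only in both symbiotic lists. The median distances were 6751.5 bp and 7579 bp (permutation test over regions with 100000 resamples, p = 0.0138, adjusted p = 0.0276 over 2 measures). Labels were permuted over regions, so this p describes these 4 libraries and not a spread between animals. In the crossed sets, called in 1 aposymbiotic and 1 symbiotic library with different numbers, the median was 7740 bp. Within 1 kb of a shared region lay 12.9% of the aposymbiotic, 7.92% of the symbiotic and 8.73% of the crossed regions. The difference in medians, symbiotic minus aposymbiotic, was 997 bp with summit windows. It was 900 bp and no longer past the threshold at equal length (permutation p = 0.0772). It reversed to -846.5 bp at a -log10 q of at least 5 (permutation p = 0.528). Widths did not differ detectably (permutation p = 0.925). A hypothesis that neighbouring regions within 10 kb share their condition stays open. Of 1069 neighbour pairs, 695 were of the same condition against 673 ± 15.05 (SD) in 10000 permutations (p = 0.0724). At equal length 338 of 632 pairs were, against 317 (permutation p = 0.0494), and in the crossed sets the permutation p was 0.290.

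The symbiotic list was the longer in both replicate numbers. Greater depth of the symbiotic libraries is argued against by the background pileup, which was lower in the symbiotic library of both pairs, with 0.806 the higher of the 2 ratios. Scaffolds of another organism present only with the alga are argued against, since the peaks on scaffolds without an aposymbiotic peak came to 0.011% of the 18125 extra symbiotic peaks. If the tags in the peak names are read as preparation dates, the symbiotic library came 1 day later in 2 of 2 pairs. The day or order of preparation then cannot be told apart from the symbiont. The median fold of the list was also higher in the symbiotic library, 1.12 times in replicate 1 and 1.13 times in replicate 2. An effect of the symbiont on the number of accessible regions stays open. It was not tested apart from preparation or from these higher folds.

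Symbiotic regions outnumbered aposymbiotic regions 3.07-fold, and 1.30-fold with lists of equal length within each number. List length and other causes cannot be told apart by this, because trimming brings the counts towards balance whatever made the symbiotic lists longer. The lowest fold called over the genome-wide background was lower in the aposymbiotic library of both numbers, with 0.963 the higher of the 2 ratios. Median folds of regions shared by all 4 libraries were also lower there, 2.98 against 3.49 in replicate 1 and 3.01 against 3.48 in replicate 2. A fold limit is thus not comparable between conditions, and a higher detection limit of the aposymbiotic libraries cannot be excluded. At their lower symbiotic fold, 72.2% of the symbiotic regions were expected above the lowest pileup called in both aposymbiotic libraries. For aposymbiotic regions and the limits of both symbiotic libraries this share was 24.8%. The lower fold limits of the aposymbiotic libraries by themselves raise the symbiotic share and lower the aposymbiotic share. Both shares carry a fold over unchanged between conditions, although folds at shared regions were lower in aposymbiotic libraries. The symbiotic share lay between the limits fixed beforehand, so the planned test was undecided. An effect of the symbiont on the ratio of symbiotic to aposymbiotic regions stays open and was not tested apart from preparation.

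The odds ratio of the replicate pairs was 2.70 within strata of strength and 2.90 within strata of width. The agreement thus did not come from strength or width alone, as these strata measure them. Strength was the mean within-list percentile of fold in the libraries that called the region, which is not a common scale across lists. Sampling of tags that is independent between libraries would leave the calls of the 2 pairs unrelated among regions of like strength. The interval within strata of strength began at 2.44. This argues against such sampling as the whole cause only as far as each stratum holds regions of like strength. The next counts also carry a fold over unchanged between libraries. With at least 95% Poisson probability in each other library taken singly, the lower fold predicted at least the lowest pileup called there. This held for 291 symbiotic and 26 aposymbiotic regions. These include 10 and 8 of the named regions. In the crossed sets the counts were 0 and 60. The odds ratio of 255 rests on the 0.5 added to the empty count, and each set had to clear the limits of different libraries, so that ratio decides nothing. An effect of the symbiont on chromatin stays open too and was not tested apart from preparation order. Condition shares that order in both pairs if the tags in the peak names are read as preparation dates.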
